A study of Homo sapiens with 12 samples.

How the data were processed

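Gene expression was measured by poly(A)-selected, paired-end RNA sequencing in 12 libraries of THP-1, an established human monocytic leukaemia line, transduced with a lentiviral non-target shRNA. The deposited values were raw read counts per Ensembl gene, 1 table per library, in the layout that featureCounts writes. Per the submitters' processing notes, the reads were handled with Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2 on the GRCh38 build. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as CCL4 and CCL4L2, therefore could not be assigned with certainty. The mitochondrial pairs MT-ND4L with MT-ND4 and MT-ATP8 with MT-ATP6 overlap on the same strand, and MT-ND6 lies opposite its neighbours.

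Groups and replicate numbers were taken from the sample titles: 5% CO2, 10% CO2, 5% CO2 with LPS and 10% CO2 with LPS, each with 3 libraries. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within each group, counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom 8.91 to 29.2), and all 12 were kept as separate samples. Total counts ranged from 17.1 to 22.2 M per library. A count floor of 3 in a library corresponded to 0.135 to 0.175 CPM, the counts-per-million scale. Binomial 95% intervals of shares (Wilson) and count floors cover counting error only, since the reads carry no molecular identifiers.

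Of 57500 gene identifiers, 40907 (71.1%) were paired with a symbol from a reference table, and these held 99.1% of all counts. Every count column was mapped to a sample, and 0 columns of per-sample values were left out. Coordinates are those of the count tables, from the first to the last exon base of a gene, on GRCh38. The mitochondrial rRNA genes MT-RNR1 and MT-RNR2 were not analysed here. XIST and Y-linked genes entered the fits and are not reported.

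Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, which left 16402 genes, TMM normalization, and the quasi-likelihood F test with robust dispersion on 1 model with 4 group means fitted to all 12 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The common biological coefficient of variation was 10.7%. Contrasts were 10% against 5% CO2 without LPS, the same with LPS, LPS against no LPS at each CO2 level, the interaction (the LPS effect at 10% minus that at 5% CO2), and CO2 averaged over LPS. Fold changes are log2 values with the standard error from the fit, and CPM values are TMM-normalized means ± SD over 3 libraries. On simulated counts for the comparison of CO2 levels without LPS (16058 genes), the test called 79.1% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 11 calls among 15858 unchanged genes. With simulated GC trends between libraries (16056 genes) it called 47.8% at 1.5-fold and 94.0% at 2-fold, and after the GC correction 77.6% and 100%. With no simulated change (16070 genes) it called 0, and DESeq2 called 2 of 16402. Changed genes were drawn only from those with a mean of at least 5 CPM, in a single simulation per setting. The rates of detection therefore do not cover genes with a lower mean. Libraries were simulated independently of each other, so the counts of false calls do not cover libraries that share variation by replicate number. The size of the simulated GC trends was preset and not taken from the data.

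Gene lists for mitochondrial function, metabolism, hypoxia, inflammation, stress responses, sterol metabolism, ribosomes, growth, monocyte identity and other cell types (39 lists in all) were fixed before the data were examined. Each list with at least 5 tested members was tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists within a contrast. It was tested again with an estimated correlation and with fry, which asks whether the genes of a list move on balance 1 way and does not compare the list with other genes. Counts of called members are given over all genes tested and adjusted over the list alone. On simulated data for CO2 without LPS (16117 genes), a raised list reached an adjusted p of 4.66e-87 with the preset and 5.65e-07 with the estimated correlation, and 0 random lists were called. Genes were simulated independently of each other, so these values do not show how the tests behave on lists whose genes move together.

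Genes named in the text follow a rule also fixed before the data were examined. It takes, per contrast, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM whose groups do not overlap, the 3 members of each called list with the smallest p, the 13 mitochondrial mRNAs, and TNF, IL1B, IL6, CXCL8, CCL2 and NFKBIA. The condition on overlap was dropped for the interaction and for CO2 averaged over LPS. Rises and falls were also limited to protein-coding and long non-coding RNA genes with an assigned symbol, without clone or read-through names. From the genes so named, 151 gene and contrast pairs were chosen for description and followed through every alternative.

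The share of counts from the mitochondrial genome (35 genes) was compared with exact two-sided permutation tests. These exact permutation tests cannot go below p = 0.1 with 3 libraries against 3, nor below 0.005 when the CO2 label is permuted within each LPS level. That permutation takes same-numbered libraries as unrelated. Moving both libraries of a number at 1 CO2 level together leaves 10 splits and a smallest p of 0.1. Other splits of the libraries were enumerated for the 4 pairwise contrasts (10 each) and drawn 100 of 200 times for the interaction and the averaged contrast.

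Alternatives fixed before the data were examined were RLE and upper-quartile normalization, no low-count filter, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, a fit of the compared groups only, the replicate number as a block, removal of mitochondrial genes, a minimum log2 change of 0.5 (glmTreat), a threshold of 0.01, and each library left out in turn. Corrections for exon GC content and for GC content and length (lowess span 0.5) were added after seeing the data. Exon sequence was read from GRCh38 at the exon coordinates of the count tables. This gave a GC content for 99.9% of genes, and merged exon length equalled the length in the count tables for 99.9%. Replicate numbers in the labels come with no statement of what they share. Deviations from group means over 5853 abundant genes correlated between libraries of the same number for all 3 pairs of LPS at 10% CO2 (r = 0.49, 0.56 and 0.26 across genes), so the numbers were taken to pair those samples. For LPS at 5% CO2 the correlations were 0.71, 0.01 and 0.27, and 0.74, 0.11 and 0.25 after the GC correction, so the pairing there depends on that correction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the remaining steps.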

Results

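The study asked how 4 h of buffered hypercapnia, an elevated CO2 level with the medium's pH held by buffering, changes transcription in monocytes at rest and after an inflammatory stimulus. THP-1 cells carrying a non-target shRNA were kept at 5% CO2 (normocapnia) or 10% CO2. LPS, a bacterial cell wall component that activates TLR4, was added at 2.5 µg/ml for the last 2 h to 1 of the groups at each CO2 level. Each of the 4 groups held 3 libraries. Total gene counts were 19.3 ± 1.99 M at 5% CO2, 20.1 ± 1.38 M at 10% CO2, 20.7 ± 0.758 M at 5% CO2 with LPS and 19.8 ± 2.08 M at 10% CO2 with LPS (mean ± SD, n = 3). The deposited values were raw counts per gene, and 16402 genes were tested. All libraries of 1 group lay beyond all libraries of the other for each gene named below as called in the 4 pairwise comparisons, a condition on which many of them were chosen. Over all called genes it held for 100% (CO2 without LPS), 97.7% (CO2 with LPS), 98.1% (LPS at 5% CO2) and 96.7% (LPS at 10% CO2). Chance gives it for 10% of genes with 3 libraries against 3, but only where no test has selected them.

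The mitochondrial genome supplied a larger share of counts at 10% than at 5% CO2. It made up 1.57% ± 0.340 of counts at 5% CO2 and 2.66% ± 0.563 at 10% CO2 without LPS (SD, n = 3). With LPS the shares were 1.55% ± 0.249 and 3.11% ± 0.95 (SD, n = 3). All 3 libraries at 10% CO2 exceeded all 3 at 5% CO2 at each LPS level, with differences of 1.08 and 1.56 percentage points. Each difference had an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows. Pooled over LPS, the difference was 1.32 points (exact permutation within LPS level, p = 0.005, the smallest these permutations can give). With both libraries of a replicate number at 1 CO2 level moved together, the exact permutation p = 0.1, the smallest those 10 splits can give. LPS itself moved the share by −0.0195 points at 5% CO2 (exact permutation p = 0.9) and by 0.458 points at 10% CO2 (exact permutation p = 0.5), less than the spread between replicates. With 1 library left out, these differences ranged from −0.15 (without 5% CO2 replicate 3) to 0.173 points (without 5% CO2 replicate 2) and from −0.0584 (without 10% CO2 with LPS replicate 2) to 0.876 points (without its replicate 3). Counting error was small beside these values: the highest single share, 4.15% at 10% CO2 with LPS (replicate 2), had a Wilson 95% interval of 4.14 to 4.16%. Because this share can also reflect RNA quality, it stands as a measured difference beside every CO2 comparison.

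**Figure D1:**
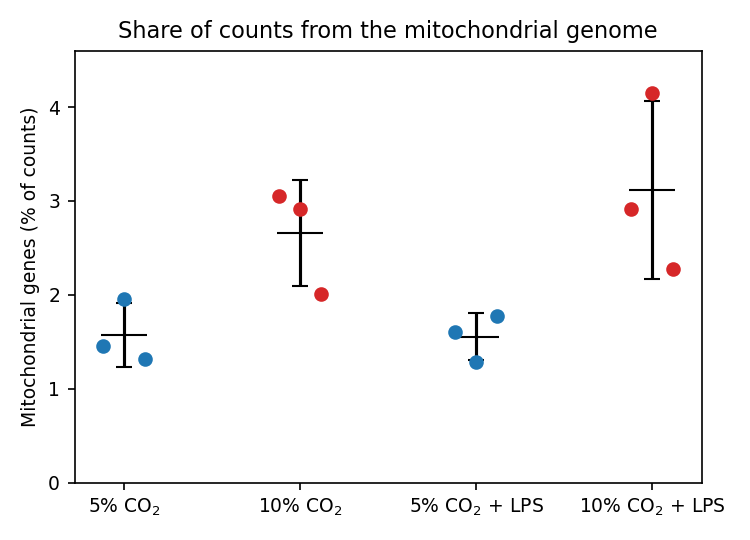
Percent of gene counts from the mitochondrial genome (vertical axis) in each of the 4 groups (horizontal axis). Points are libraries, the wide line is the group mean and the error bar is ±1 SD (n = 3). The libraries at 10% CO2 range from 2.01% to 4.15% and lie above the libraries at 5% CO2, which range from 1.28% to 1.96%.

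The first comparison asked what 10% CO2 does to resting THP-1 cells. Genes of serine synthesis and ribosome assembly were among those that rose: PSAT1 (log2 change 0.51 ± 0.09 SE, adjusted p = 0.018) and PSPH (0.45 ± 0.09, adjusted p = 0.0222), enzymes of serine synthesis, and RRP9 and WDR12, factors of ribosome assembly (0.56 ± 0.10 and 0.51 ± 0.09, adjusted p = 0.018 for both). The glycoprotein hormone gene STC2 rose by 0.73 ± 0.14 and the co-chaperone gene FKBP4 by 0.67 ± 0.14. INSIG1, a brake on sterol synthesis that is itself a target of SREBP, fell by 0.65 (SE 0.10, adjusted p = 0.0124), from 69.7 ± 6.02 to 44.5 ± 4.00 CPM (SD, n = 3). BCL3 and RELB, both on the list of NF-κB targets, fell by 0.85 (SE 0.17) and 0.61 (SE 0.13). In all, 240 genes were called, 131 higher and 109 lower at 10% CO2, and 15 of them changed at least 2-fold. The count was 0 without 10% CO2 replicate 2, 1 without 5% CO2 replicate 1, 4 without 5% CO2 replicate 2, 139 without 5% CO2 replicate 3, 143 without 10% CO2 with LPS replicate 3 and 511 without 10% CO2 replicate 1. It was 71 with only the compared groups in the fit, 572 with no low-count filter, 844 after a GC correction and 696 by DESeq2.

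Among called genes under the naming rule (mean of at least 5 CPM), the largest rise was that of SERPINB2. This gene encodes the plasminogen activator inhibitor PAI-2 (ENSG00000197632, chromosome 18, 63871692 to 63903890, GRCh38). It went from 6.28 ± 1.43 to 12.4 ± 2.61 CPM (log2 change 0.98 ± 0.20, adjusted p = 0.0232). POLR3G, a subunit of RNA polymerase III, rose by 0.90 ± 0.20, NARS2, the mitochondrial asparaginyl-tRNA synthetase, by 0.82 ± 0.13, and CBR1, a carbonyl reductase, by 0.73 ± 0.18. In that set the largest fall was that of RFX8 (ENSG00000196460, chromosome 2, 101397361 to 101474703), from 13.6 ± 1.00 to 6.12 ± 1.48 CPM (log2 change −1.15 ± 0.18, adjusted p = 0.0124). B3GNT7, a glycosyltransferase gene, had a change of −0.98 ± 0.21. Genes linked to p53 and apoptosis, TP53INP1 and BMF, fell by 0.93 (SE 0.19) and 0.89 (SE 0.20). Each called gene named for this comparison lost its call without 10% CO2 replicate 2, with adjusted p from 0.122 for RFX8 to 0.257 for ZFP36, and without 5% CO2 replicate 1, with adjusted p from 0.0691 for INSIG1 to 0.211 for CBR1.

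By list, 6 of 36 ribosome biogenesis factors rose and 0 fell, or 21 adjusted over the list alone (median log2 change 0.21, camera adjusted p = 1.42e-14, and adjusted p = 0.143 with an estimated correlation). BOP1 was a further member, at 0.44 ± 0.10. Of 40 integrated stress response genes, the amino acid and tRNA synthetase programme under ATF4, 4 rose and 0 fell, or 15 adjusted over the list alone (camera adjusted p = 2.89e-08, and adjusted p = 0.143 with an estimated correlation). Of 76 mitochondrial ribosome genes 3 rose, or 17 adjusted over the list alone, among them MRPL15 (0.41 ± 0.09) and MRPL33 (0.40 ± 0.09). That list had a camera adjusted p = 3.89e-12, and adjusted p = 0.356 with an estimated correlation. Of 31 genes for mitochondrial transcription, MTERF3 alone rose (0.54 ± 0.12), or 2 genes adjusted over the list alone (camera adjusted p = 0.000202, and adjusted p = 0.143 with an estimated correlation). Of 25 heat shock genes FKBP4 alone rose, or 10 adjusted over the list alone (camera adjusted p = 5.63e-06, and adjusted p = 0.557 with an estimated correlation).

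None of the 13 mRNAs encoded by mitochondrial DNA passed the test over all genes, and 7 did so adjusted over the list alone, all higher at 10% CO2. Their median log2 change was 0.68 (camera adjusted p = 6.31e-08, and adjusted p = 0.441 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, had 1.02 ± 0.30 (adjusted p = 0.133), MT-ND5 0.68 ± 0.20 (adjusted p = 0.119) and MT-ND3 0.05 ± 0.11 (adjusted p = 0.852). In the same libraries the mitochondrial share of counts was higher by 1.08 points. By DESeq2, MT-CO1 and MT-ND5 passed (adjusted p = 0.023 and 0.00529).

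Among lists with negative medians, immediate early genes had 2 falls of 32, BTG2 (−0.67 ± 0.13) and ZFP36 (−0.46 ± 0.11), a factor that speeds decay of cytokine mRNAs. Adjusted over the list alone 8 fell (median −0.24, camera adjusted p = 5.21e-06, and adjusted p = 0.521 with an estimated correlation). Interferon-stimulated genes had 2 falls of 52, the antiviral GTPase gene MX1 (−0.54 ± 0.13) among them, or 5 adjusted over the list alone (camera adjusted p = 2.48e-05, and adjusted p = 0.560 with an estimated correlation). Sterol synthesis genes had 2 falls of 31, INSIG1 and IDI1 (−0.41 ± 0.09), with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000841, and adjusted p = 0.557 with an estimated correlation). Of 57 NF-κB targets 5 fell and SERPINB2 rose. Adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 0.00798, and adjusted p = 0.695 with an estimated correlation). With LPS the mean of SERPINB2 was lower, 1.63 against 6.28 CPM at 5% CO2 and 2.69 against 12.4 CPM at 10% CO2. Of 39 TLR feedback genes BCL3 and ZFP36 fell, or 3 adjusted over the list alone (camera adjusted p = 0.00539, and adjusted p = 0.695 with an estimated correlation). The cytokine genes TNF (−0.92 ± 0.27, adjusted p = 0.119), CXCL8 (−0.66 ± 0.22, adjusted p = 0.153) and IL1B (−0.12 ± 0.17, adjusted p = 0.756) did not pass, though DESeq2 called TNF and CXCL8 (adjusted p = 0.0282 and 0.0125). The NF-κB and TLR feedback lists lost their calls without 5% CO2 replicate 1 (camera adjusted p = 0.206 and 0.309) and without 10% CO2 replicate 2 (0.138 and 0.233), and with an estimated correlation 0 of the 14 called lists passed.

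The same comparison in LPS-treated cells asked how 10% CO2 acts on stimulated monocytes. Chaperone genes rose together: HSPH1, which encodes an HSP110 chaperone (ENSG00000120694, chromosome 13, 31134974 to 31162388), went from 152 ± 51.5 to 412 ± 138 CPM (log2 change 1.43 ± 0.31, adjusted p = 0.0238). FKBP4 rose by 0.87 ± 0.14, HSPD1, the mitochondrial HSP60, by 0.69 ± 0.12 and AHSA1, an activator of HSP90, by 0.81 ± 0.15. Of 25 heat shock genes 13 rose and 0 fell, or 19 adjusted over the list alone (median 0.51, camera adjusted p = 2.22e-13, and adjusted p = 0.357 with an estimated correlation). Transcripts of mitochondrial DNA rose as well, with 6 of 13 called and 12 adjusted over the list alone (median 1.06, camera adjusted p = 1.63e-10, and adjusted p = 0.357 with an estimated correlation). In all, 1435 genes were called, 703 higher and 732 lower at 10% CO2, and 129 changed at least 2-fold.

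Among the mitochondrial mRNAs, MT-CO1 (ENSG00000198804, mitochondrial genome, 5904 to 7445) rose by 1.28 ± 0.30 (adjusted p = 0.0361), MT-ND5 by 1.06 ± 0.20 (adjusted p = 0.0125) and MT-ND4L by 1.30 ± 0.25 (adjusted p = 0.0155). MT-ND4L shares bases with MT-ND4, so its reads cannot be separated from those of its neighbour with certainty. Without 5% CO2 with LPS replicate 1, MT-CO1, MT-ND5 and MT-ND4L lost their calls (adjusted p = 0.112, 0.0543 and 0.0669), as they did without its replicate 2 (0.13, 0.0582 and 0.0611). MT-CO1 also lost its call without 10% CO2 with LPS replicate 2 (adjusted p = 0.117) or 1 (0.063), 5% CO2 replicate 1 (0.0526) and 5% CO2 with LPS replicate 3 (0.0502). MT-ND3 had 0.16 ± 0.11 (adjusted p = 0.377). The mitochondrial share of counts was higher by 1.56 points in the same libraries. The genes TFAM and MTERF3, whose proteins act on mitochondrial DNA, rose by 0.33 ± 0.10 and 0.55 ± 0.12, and 4 of the 31 mitochondrial transcription genes rose in all, or 5 adjusted over the list alone (camera adjusted p = 0.00798, and adjusted p = 0.357 with an estimated correlation). TFAM lost its call after the GC correction (0.21, adjusted p = 0.0615) and without any of 6 libraries (adjusted p 0.0524 to 0.167): 10% CO2 replicate 2, replicates 1 and 2 of 5% CO2 with LPS, and all 3 of 10% CO2 with LPS. MTERF3 lost its call without 5% CO2 with LPS replicate 1 (adjusted p = 0.0534) or 2 (0.0676) and without 10% CO2 with LPS replicate 2 (0.0701), and MRPL33 without 5% CO2 with LPS replicate 1 (0.0915) and 10% CO2 with LPS replicate 2 (0.0701). Of 76 mitochondrial ribosome genes 13 rose, or 14 adjusted over the list alone, MRPL33 among them at 0.39 ± 0.09 (camera adjusted p = 3.13e-05, and adjusted p = 0.542 with an estimated correlation).

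**Figure D2:**
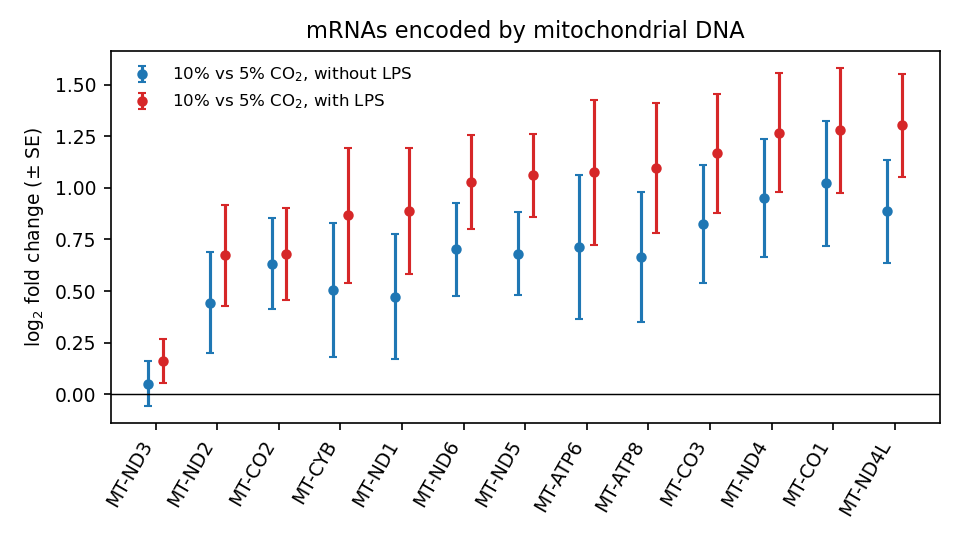
log2 fold change at 10% against 5% CO2 (vertical axis, error bars ±1 SE of the fit, 3 libraries per group) for each of the 13 mRNAs encoded by mitochondrial DNA (horizontal axis), without LPS (blue) and with LPS (red). MT-ND3 is lowest at 0.05 and 0.16, and MT-CO1 reaches 1.02 and 1.28.

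Among called genes under the naming rule (mean of at least 5 CPM), the largest rises with LPS were in CRIM1 and SLC16A9. CRIM1, a BMP-binding membrane protein gene (ENSG00000150938, chromosome 2, 36355926 to 36551135), went from 7.16 ± 3.48 to 26.5 ± 7.86 CPM (log2 change 1.88 ± 0.28, adjusted p = 0.00314). SLC16A9, a monocarboxylate transporter family gene, rose by 1.66 ± 0.28. The lymphangiogenic growth factor gene VEGFC rose by 1.49 ± 0.34 and PSTPIP2, a cytoskeletal adaptor gene, by 1.46 ± 0.29. PRR12 (ENSG00000126464, chromosome 19, 49591643 to 49626439) had the smallest adjusted p among the falls described here, from 25.5 ± 5.42 to 11.8 ± 0.949 CPM (log2 change −1.11 ± 0.15, adjusted p = 0.00089). B3GNT7 fell by 1.24 (SE 0.24), ATOSB by 1.16 (SE 0.20) and OCLN, the tight junction gene for occludin, by 1.13 (SE 0.19). Without 10% CO2 with LPS replicate 2, HSPH1, VEGFC and PSTPIP2 lost their calls (adjusted p = 0.0833, 0.098 and 0.061), as they did without 5% CO2 with LPS replicate 1 (0.105, 0.0981 and 0.0664), and HSPH1 and PSTPIP2 also without its replicate 2 (0.0857 and 0.0526).

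The serine synthesis genes PSPH and PSAT1 rose again, by 0.61 ± 0.10 and 0.51 ± 0.09. The tRNA synthetase gene NARS1 rose by 0.46 ± 0.09 and was not called without LPS (0.30 ± 0.09, adjusted p = 0.098). These 3 belong to the 10 of 40 integrated stress response genes that rose, with 14 adjusted over the list alone and 0 falls (camera adjusted p = 0.000403, and adjusted p = 0.357 with an estimated correlation). Of 36 ribosome biogenesis genes 10 rose, or 17 adjusted over the list alone, with POLR1A, the catalytic subunit of RNA polymerase I, at 0.60 ± 0.11 and RRP9 at 0.45 ± 0.10 (camera adjusted p = 3.66e-09, and adjusted p = 0.357 with an estimated correlation). Of 57 NF-κB targets 10 rose and 1 fell, or 12 and 3 adjusted over the list alone. TNIP3 rose by 0.81 ± 0.15, GCH1 by 0.71 ± 0.13 and RIPK2, a kinase of NOD signalling, by 0.56 ± 0.10, and ZFP36 was the gene that fell (−0.51 ± 0.11). This list had a camera adjusted p = 0.000371, and adjusted p = 0.542 with an estimated correlation. The cytokine genes TNF (−0.10 ± 0.24, adjusted p = 0.839) and IL1B (0.11 ± 0.15, adjusted p = 0.699) did not pass, and IL1B stood at 3782 ± 680 CPM at 5% and 4073 ± 558 CPM at 10% CO2. RRP9 and ZFP36 lost their calls without 5% CO2 with LPS replicate 2 (adjusted p = 0.0596 and 0.0582), and RRP9 also without 10% CO2 with LPS replicate 2 (0.0542).

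Sterol, hypoxia and monocyte genes lay on the lower side. Of 31 sterol synthesis genes 5 fell and STARD4, a sterol carrier gene, rose (0.51 ± 0.10), or 9 and 2 adjusted over the list alone. DHCR7, which makes the last step to cholesterol, fell by 0.68 (SE 0.13) and IDI1 by 0.49 (SE 0.09), with a camera adjusted p = 0.000824 for the list, and adjusted p = 0.542 with an estimated correlation. Of 29 hypoxia genes 4 fell, among them ZNF395 (−0.86 ± 0.18) and the mitophagy receptor gene BNIP3L (−0.49 ± 0.12). Adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.00798, and adjusted p = 0.494 with an estimated correlation). Of 39 monocyte genes 3 fell, or 1 adjusted over the list alone, with CEBPA, a myeloid transcription factor gene, at −0.88 ± 0.18 and CSF1R, the receptor for M-CSF, at −0.62 ± 0.17 (camera adjusted p = 0.00798, and adjusted p = 0.542 with an estimated correlation). Immediate early genes had 2 falls of 32, ZFP36 and MYC (−0.42 ± 0.10), and also 2 adjusted over the list alone (camera adjusted p = 0.00506, and adjusted p = 0.647 with an estimated correlation). CSF1R lost its call after the GC correction (−0.52, adjusted p = 0.113), as did the lists of immediate early and monocyte genes (camera adjusted p = 0.0867 and 0.059), which were also lost without 5% CO2 with LPS replicate 1 (0.0547 and 0.072). Without 10% CO2 with LPS replicate 2, BNIP3L (adjusted p = 0.143), CEBPA (0.076), CSF1R (0.162), MYC (0.129) and STARD4 (0.064) lost their calls. Without 5% CO2 with LPS replicate 1 these were BNIP3L (0.0685), CEBPA (0.0612), CSF1R (0.158) and MYC (0.116), and without its replicate 2 BNIP3L (0.0766), ZNF395 (0.0525), ZFP36 (0.0582) and CSF1R (0.102). MYC was also lost without 10% CO2 with LPS replicate 3 (0.0547), and CSF1R without that library (0.106), 5% CO2 replicate 2 (0.0617) or 10% CO2 replicates 1 and 3 (0.0662 and 0.0723).

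The count of 1435 fell to 271 without 10% CO2 with LPS replicate 2, 414 and 458 without 5% CO2 with LPS replicates 1 and 2, and 917 without 10% CO2 with LPS replicate 3. With an estimated correlation 0 of the 18 called lists passed.

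**Figure D3:**
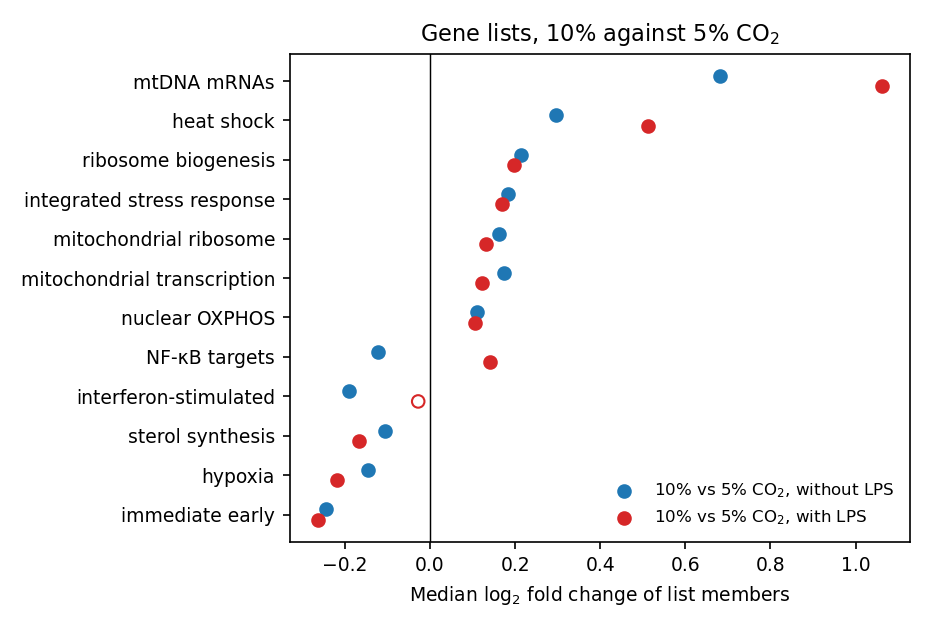
Median log2 fold change of the tested members (horizontal axis) of 12 gene lists (vertical axis) at 10% against 5% CO2, without LPS (blue) and with LPS (red). Filled points are lists with a camera adjusted p under 0.05 at the preset correlation and the open point did not pass; heat shock genes lie at 0.30 and 0.51, and NF-κB targets at −0.12 and 0.14.

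Whether both CO2 responses involve the same genes was asked by comparing them directly, since they share no library. Both comparisons called 92 genes higher, where independent lists of the same lengths would share 5.61, and 65 genes lower, where they would share 4.86. A further gene was called in opposite directions. These shared counts are not stable when a library is left out, which also weakens the test. CO2 without LPS called 0 genes without 10% CO2 replicate 2, and 1 and 4 without 5% CO2 replicates 1 and 2, so no more can be shared there. Of the 1517 genes called in either, 90.8% had the same sign in both. The number called in either was 415 without 10% CO2 with LPS replicate 2, and 544 and 574 without 5% CO2 with LPS replicates 1 and 2. The share with the same sign moved less: it was 89.4% without 10% CO2 replicate 2 and lowest, 83.3%, without 10% CO2 replicate 1. Log2 changes of the 1517 genes correlated at 0.716 across genes, which are not independent replicates. Over all genes tested 69.6% had the same sign and the covariance was 0.0520, above the highest of 0.0388 in size among the other regroupings drawn of the CO2 labels within LPS level. The regrouping with that value keeps the real labels at 1 LPS level. These regroupings and the independent lists take the libraries of both comparisons as unrelated, but replicate numbers may pair them at 10% CO2. With both libraries of a number moved together, the 9 other splits gave covariances of up to 0.0322, all above 0, and up to 67.2% of genes with the same sign.

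Averaging CO2 over both LPS levels used all 12 libraries and called 2748 genes, 1322 higher and 1426 lower at 10% CO2. The fit took these libraries as unrelated, but replicate numbers may pair libraries across LPS at 10% CO2. Standard errors and adjusted p of this contrast, its lists included, may therefore be too small. SLC16A9 (1.53 ± 0.23), HSPH1 (1.17 ± 0.22), MT-CO1 (1.15 ± 0.21) and MT-ND4 (1.11 ± 0.20) were among the largest rises. DHRS3 (−1.15 ± 0.29), RFX8 (−1.12 ± 0.13), ATOSB (−0.96 ± 0.13) and the transcription factor gene RUNX3 (−0.92 ± 0.18) were among the largest falls. PSPH (0.53 ± 0.07) and PSAT1 (0.51 ± 0.06) rose and INSIG1 fell (−0.55 ± 0.07), each at adjusted p = 0.000138. STC2 (0.63 ± 0.10) and FKBP4 (0.77 ± 0.10) also rose. MT-ND3 had 0.11 ± 0.08 (adjusted p = 0.366).

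Over both LPS levels, 23 of 36 ribosome biogenesis genes rose and 0 fell, or 30 adjusted over the list alone (camera adjusted p = 2.82e-14, and adjusted p = 0.165 with an estimated correlation). Of 40 integrated stress response genes 18 rose and 0 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 2.35e-07, and adjusted p = 0.165 with an estimated correlation). Of 76 mitochondrial ribosome genes 25 rose, or 31 adjusted over the list alone, MRPL34 among them at 0.42 ± 0.08 (camera adjusted p = 2.92e-10, and adjusted p = 0.312 with an estimated correlation). Mitochondrial mRNAs had 9 rises of 13, or 12 adjusted over the list alone, and heat shock genes 12 of 25, or 18 adjusted over the list alone (camera adjusted p = 8.34e-12 and 4.35e-12, and adjusted p = 0.299 with an estimated correlation for both). Of 31 mitochondrial transcription genes 9 rose, or 11 adjusted over the list alone, with MTERF3 at 0.54 ± 0.09 (camera adjusted p = 0.000335, and adjusted p = 0.165 with an estimated correlation). Sterol synthesis genes had 8 falls and 2 rises of 31, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.452 with an estimated correlation). Immediate early genes had 10 falls of 32, or 12 adjusted over the list alone, including JUND (−0.60 ± 0.13) and ZFP36 (−0.48 ± 0.08), with a camera adjusted p = 2.17e-05, and adjusted p = 0.476 with an estimated correlation. Of the 20 called genes described for this contrast, 18 had the CO2 groups apart at both LPS levels and DHRS3 and JUND did not. Of all 2748 called genes 1367 (49.7%) had them apart at both levels. The count of 2748 was 1664 without 10% CO2 replicate 2, 1687 without 10% CO2 with LPS replicate 2 and 1801 without 5% CO2 with LPS replicate 1, and with an estimated correlation 0 of the 16 called lists passed. DHRS3 lost its call without any of 7 libraries (adjusted p 0.0501 to 0.0697): 5% CO2 replicate 2, 10% CO2 replicates 2 and 3, 5% CO2 with LPS replicates 1 and 2, and 10% CO2 with LPS replicates 2 and 3.

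LPS at 5% CO2 gives the reference inflammatory response. Cytokine and chemokine genes rose steeply: TNF went from 28.1 ± 6.03 to 1053 ± 52.5 CPM (log2 change 5.23 ± 0.29, adjusted p = 3.88e-07), IL1B from 19.2 ± 2.98 to 3782 ± 680 CPM (7.62 ± 0.20, adjusted p = 1.7e-12), CXCL8 by 7.74 ± 0.25 and the monocyte attractant CCL2 by 3.45 ± 0.36. IL6 had 0 counts in all unstimulated libraries and 1.40 ± 0.683 CPM with LPS, here without TMM scaling, at least 8.91-fold above the floor of 3 counts per library. Among the largest rises were those of CCL4 and its near-identical copy CCL4L2 (9.70 ± 0.18 and 9.70 ± 0.16, reads that may be divided between the copies), TNFAIP6 (9.28 ± 0.29), CXCL2 (8.35 ± 0.19) and CXCL10 (8.23 ± 0.61). Among the largest falls were those of CCR2, the receptor for CCL2 (ENSG00000121807, chromosome 3, 46353734 to 46360928), from 177 ± 52.1 to 14.4 ± 5.60 CPM (−3.63 ± 0.42), NFE2 (−3.22 ± 0.19), MYC and WNT6 (both −2.74, SE 0.11 and 0.23) and CCR1 (−2.64 ± 0.17). In all, 4092 genes were called, 1940 higher and 2152 lower, and 1280 changed at least 2-fold.

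At 5% CO2, 53 of 57 NF-κB targets rose and 1 fell, or 54 and 1 adjusted over the list alone (median 3.07, camera adjusted p = 7.68e-174, and adjusted p = 0.000258 with an estimated correlation). NFKBIZ (ENSG00000144802, chromosome 3, 101827991 to 101861022) rose by 7.40 ± 0.12, the dendritic cell marker CD83 by 5.41 ± 0.10, the apoptosis inhibitor BIRC3 by 5.45 ± 0.16 and NFKBIA, which encodes IκBα, by 4.04 ± 0.12. Of 45 cytokine genes 31 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 5.15e-89, and adjusted p = 0.000154 with an estimated correlation). Of 32 immediate early genes 27 rose and 2 fell, or 27 and 3 adjusted over the list alone, with EGR2 at 6.76 ± 0.15 and CCN2 at 6.66 ± 0.13. That list had a camera adjusted p = 9.2e-60, and adjusted p = 0.00672 with an estimated correlation. Of 39 TLR feedback genes 25 rose and 5 fell, or 26 and 8 adjusted over the list alone, and of 24 p53 targets 10 rose and 2 fell, the same counts adjusted over the list alone, among them BTG2 (5.57 ± 0.14), PLK3 (1.71 ± 0.14) and PMAIP1 (1.27 ± 0.10). These last lists had camera adjusted p = 1.23e-47 and 7.65e-05, and adjusted p = 0.011 with an estimated correlation for both.

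The other 6 lists called for LPS at 5% CO2 lost the call with an estimated correlation. Cytosolic ribosomal protein genes had 55 rises of 75, or 69 adjusted over the list alone (median 0.26, camera adjusted p = 1.3e-05, and adjusted p = 0.920 with an estimated correlation). Interferon-stimulated genes had 15 rises and 2 falls of 52, or 15 and 3 adjusted over the list alone, led by GBP2 at 3.49 ± 0.15 (camera adjusted p = 0.000197, and adjusted p = 0.828 with an estimated correlation). TLR pathway genes had 12 rises and 4 falls of 32, or 13 and 6 adjusted over the list alone, led by the kinase gene IRAK2 at 4.64 ± 0.18 (camera adjusted p = 0.000814, and adjusted p = 0.408 with an estimated correlation). NRF2 targets had 8 rises of 28, also 8 adjusted over the list alone, with NFE2L2 (2.52 ± 0.09), FTH1 (2.24 ± 0.18) and SQSTM1 (1.67 ± 0.21) among them (camera adjusted p = 0.0173, and adjusted p = 0.828 with an estimated correlation). Integrated stress response genes had 13 rises and 3 falls of 40, or 17 and 4 adjusted over the list alone, led by PPP1R15A at 4.62 ± 0.19 (camera adjusted p = 0.0181, and adjusted p = 0.522 with an estimated correlation). Heat shock genes had 5 rises of 25, also 5 adjusted over the list alone (camera adjusted p = 0.0458, and adjusted p = 0.920 with an estimated correlation). Without 5% CO2 with LPS replicate 3, the heat shock and NRF2 lists lost their calls (camera adjusted p = 0.198 and 0.0529), and for LPS at 5% CO2 the heat shock list also without 5% CO2 replicate 2 (0.0595) or 10% CO2 replicate 1 (0.0653) and after the GC correction (0.0548) or with the replicate number as a block (0.0806).

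LPS at 10% CO2 raised the same inflammatory genes. TNF rose by 6.05 ± 0.30 (adjusted p = 1.18e-07) to 982 ± 81.6 CPM, IL1B by 7.85 ± 0.20, CXCL8 by 8.42 ± 0.26, CCL2 by 3.81 ± 0.38 and NFKBIA by 4.29 ± 0.12. IL6 had 0 counts without LPS and 1.96 ± 0.622 CPM with it, also without TMM scaling, at least 13-fold above the floor of 3 counts per library. Among the largest rises were those of TNFAIP6 (9.34 ± 0.27), SHROOM3 (9.07 ± 0.22), CXCL10 (9.06 ± 0.59) and CXCL1 (8.79 ± 0.25). Among the largest falls were those of CCR2 (−4.58 ± 0.45), NFE2 (−3.36 ± 0.21), B3GNT8 (−3.24 ± 0.21), MYC (−3.23 ± 0.11) and GFI1, a myeloid repressor gene (−2.90 ± 0.15). In all, 5773 genes were called, 2727 higher and 3046 lower, and 1747 changed at least 2-fold. Values for this comparison come from the fit that does not use the pairing by replicate number. With that number as a block 6375 genes were called.

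For LPS at 10% CO2, 52 of 57 NF-κB targets rose and 1 fell, or 54 and 1 adjusted over the list alone (median 3.59, camera adjusted p = 2.78e-153, and adjusted p = 0.000455 with an estimated correlation). Cytokine genes had 31 rises and 4 falls of 45, the same counts adjusted over the list alone, and immediate early genes 27 and 2 of 32, or 28 and 2 adjusted over the list alone (camera adjusted p = 2.26e-73 and 5.99e-46, and adjusted p = 0.000269 and adjusted p = 0.0136 with an estimated correlation). TLR feedback genes had 26 rises and 10 falls of 39, the same counts adjusted over the list alone, and p53 targets 10 and 5 of 24, or 10 and 6 adjusted over the list alone, with TP53INP1 at 2.64 ± 0.18 (camera adjusted p = 1.56e-36 and 0.000695, and adjusted p = 0.0241 with an estimated correlation for both). Heat shock genes had 20 rises of 25, also 20 adjusted over the list alone, including DNAJB4 (1.27 ± 0.16), DNAJB6 (0.96 ± 0.09) and HSP90AB1 (0.59 ± 0.09), with a camera adjusted p = 0.000749, and adjusted p = 0.897 with an estimated correlation. Interferon-stimulated genes had 22 rises and 2 falls of 52, or 24 and 3 adjusted over the list alone, with GBP2 at 4.53 ± 0.16 (camera adjusted p = 4.54e-06, and adjusted p = 0.799 with an estimated correlation). Cytosolic ribosomal protein genes had 60 rises of 75, or 68 adjusted over the list alone, TLR pathway genes 14 rises and 5 falls of 32 and NRF2 targets 11 and 3 of 28, the same counts adjusted over the list alone for both. These lists had camera adjusted p = 0.000134, 0.00104 and 0.0371, and adjusted p = 0.897, 0.399 and 0.897 with an estimated correlation, and NRF2 targets lost the call without 10% CO2 replicate 2 (0.0548).

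The LPS responses at both CO2 levels shared 1744 higher and 1780 lower genes, against 323 and 399.6 for independent lists of those lengths, with 0 called in opposite directions. They share no library. Of 6341 genes called in either, 98.0% had the same sign, against 81.0% of all genes tested, and log2 changes of those called correlated at 0.948 across genes.

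The interaction asked whether the LPS response differed between CO2 levels, and 4 genes passed, all with a larger LPS rise at 10% CO2. HIVEP2, a zinc finger transcription factor gene that binds κB-like sites (ENSG00000010818, chromosome 6, 142751467 to 142945201), went from 41.7 ± 1.54 to 121 ± 18.1 CPM at 5% CO2 and from 30.2 ± 3.00 to 197 ± 1.39 CPM at 10% CO2 (interaction 1.17 ± 0.14, adjusted p = 0.00255). PDGFA, a platelet-derived growth factor gene (ENSG00000197461, chromosome 7, 497258 to 520296), went from 5.42 ± 0.615 to 34.3 ± 6.58 CPM and from 3.35 ± 0.292 to 53.4 ± 7.01 CPM (1.33 ± 0.22, adjusted p = 0.046). The hyaluronan receptor gene CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402) went from 115 ± 14.8 to 235 ± 28.3 CPM and from 79.9 ± 11.4 to 367 ± 56.7 CPM (1.17 ± 0.19, adjusted p = 0.046). STARD4 (ENSG00000164211, chromosome 5, 111496033 to 111512590) went from 19.1 ± 1.07 to 66.6 ± 5.30 CPM and from 14.4 ± 0.259 to 94.7 ± 14.6 CPM (0.92 ± 0.15, adjusted p = 0.046). At 10% CO2 each of the 4 had a lower mean without LPS and a higher mean with LPS, and both enter the interaction.

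Of 57 NF-κB targets, CD44 alone passed over all genes and 11 passed adjusted over the list alone, all with a positive interaction (median 0.31, camera adjusted p = 1.36e-11, and adjusted p = 0.900 with an estimated correlation). KYNU had 0.87 ± 0.20 (adjusted p = 0.231) and RIPK2 0.61 ± 0.15 (adjusted p = 0.253). Heat shock genes had 0 of 25 called (median 0.24, camera adjusted p = 0.0001, and adjusted p = 0.900 with an estimated correlation), also 0 adjusted over the list alone. Interferon-stimulated genes had 0 of 52 called and 2 adjusted over the list alone (median 0.17, camera adjusted p = 0.000318, and adjusted p = 0.900 with an estimated correlation), with GBP2 at 1.04 ± 0.22 (adjusted p = 0.146). TNF had 0.82 ± 0.35 (adjusted p = 0.807). At an unadjusted p under 0.05 edgeR gave 989 of 16402 genes, where a share of 0.05 is reached with no change at all. DESeq2 called 53 after adjustment.

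HIVEP2 kept its interaction call in every fit that tests against no change, each library left out in turn included (adjusted p 4.67e-11 to 0.0189). Against a minimum log2 change of 0.5 (glmTreat) 0 genes passed. CD44, PDGFA and STARD4 each lost the call without any of 9 libraries, with adjusted p of up to 0.238 (without 10% CO2 replicate 2). All 3 kept it without 5% CO2 with LPS replicate 3 or 10% CO2 replicate 1, CD44 also without 10% CO2 with LPS replicate 3, and PDGFA and STARD4 also without 10% CO2 with LPS replicate 1. All 3 lost it after RLE normalization (adjusted p = 0.0507) and with the stricter low-count filter (0.0676). PDGFA and STARD4 lost it after upper-quartile normalization (0.0513 and 0.0744), and CD44 and STARD4 after the GC correction (0.128 and 0.131) and the GC and length correction (0.174 and 0.0854). The count of 4 was 37 without 5% CO2 with LPS replicate 3, 26 without 10% CO2 replicate 1, 6 without 10% CO2 with LPS replicate 1, 2 without 10% CO2 with LPS replicate 3 and 1 without each of the other libraries. The heat shock list lost its interaction call without 10% CO2 with LPS replicate 2 (camera adjusted p = 0.105), and the interferon list without 10% CO2 replicate 1 (0.196) or 10% CO2 with LPS replicate 3 (0.081).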

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

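The tests with the GC correction were chosen only after the result was seen, and those that leave out a library were planned. The items below stand out because the LPS response differed between 10% and 5% CO2 in the test of the CO2 by LPS interaction itself. The genes were HIVEP2 (interaction 1.17), CD44 (1.17), PDGFA (1.33) and STARD4 (0.92, all log2), each with a larger LPS rise at 10% CO2. The lists, by the median log2 interaction of their members, were NF-κB targets (0.31), cytokines and chemokines (0.23), interferon-stimulated genes (0.17), heat shock genes (0.24), replication-dependent histone genes (0.36) and monocyte genes (−0.11). All 6 lists had an adjusted p = 0.900 with an estimated correlation. After the GC correction the cytokine and monocyte lists no longer passed (camera adjusted p = 0.0717 and 0.157). With 1 library left out, the cytokine list was lost without any of 8 libraries, the monocyte list without any of 7 and the histone list without any of 5 (camera adjusted p of up to 0.484, 0.380 and 0.116).

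The larger LPS rise of NF-κB targets at 10% CO2 may be technical or may follow the CO2 level. It joins a lower level without LPS with a higher level with LPS: the median change at 10% CO2 was −0.12 and 0.14. It is therefore not a measure of the stimulated level alone. A GC trend between libraries as the whole cause is argued against, since the median interaction was 0.29 after the GC correction, 93.2% of the 0.31 before it. A single library as its whole source is argued against as well: the lowest median with 1 library left out was 0.19, without 10% CO2 replicate 2, and the highest was 0.35. What stays open is whether 3 libraries per group, whose independence the labels do not state, carry the difference, because the list had an adjusted p = 0.900 with an estimated correlation. A CO2 effect on the NF-κB response stays a hypothesis found and tested on the same libraries.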

How the results depend on the processing

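The GC and length corrections, alone or with the replicate block, were tests chosen only after the result was seen; the other alternatives were planned. Counts of called genes below are in the order CO2 without LPS (240), CO2 with LPS (1435), LPS at 5% CO2 (4092), LPS at 10% CO2 (5773), interaction (4) and CO2 averaged over LPS (2748), and apart from the block and the ranges over left-out libraries only values that moved by over 1.5 times are given. The cause was not tested except where fewer samples or a stricter threshold set it. An adjusted p under 0.01 gave 1 gene for CO2 without LPS, 340 for CO2 with LPS, 2610 for LPS at 5% CO2, 1 for the interaction and 1063 for CO2 averaged. A minimum log2 change of 0.5 (glmTreat, edgeR) gave 0, 1, 1303, 1894, 0 and 0. For CO2 without LPS, no low-count filter gave 572, the GC correction 844, GC and length 862, only the compared groups 71 and DESeq2 696. For the interaction, RLE gave 1, upper-quartile 2, no filter 108, the stricter filter 1 and DESeq2 53.

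The replicate number as a block gave 699, 2121, 4622, 6375, 11 and 3520 genes, without mitochondrial genes 657 (CO2 without LPS) and 10 (interaction), and with the GC correction 2008, 2979, 32 (interaction) and 4652 (averaged). By correlations without a GC correction, only for LPS at 10% CO2 were numbers taken to pair the samples, and there the block changed no list's call. Elsewhere it ended 1 list call in the text, heat shock for LPS at 5% CO2 (0.0806). Same-number correlations elsewhere were 0.47, 0.24 and −0.43 for CO2 without LPS, 0.67, −0.28 and −0.12 for CO2 with LPS, and 0.71, 0.01 and 0.27 for LPS at 5% CO2 (0.74, 0.11 and 0.25 after the GC correction), and not every library correlated best with its own number. Libraries of replicate 1 correlated between all groups (0.26 to 0.71), across CO2 levels too, so a source of variation shared by them stays open. In 5% CO2 with LPS, replicate 3 correlated best with 10% CO2 with LPS replicate 2 (0.63). Replicate 2 of that group did so with 10% CO2 with LPS replicate 3 (0.45). The block by number may therefore misplace these libraries. Called lists went from 14, 18, 11, 10, 6 and 16 to 0, 0, 5, 5, 0 and 0 with an estimated correlation. By fry they were 4 for CO2 without LPS, 6 for CO2 with LPS, 18 for LPS at 10% CO2 and 0 for the interaction. The 4 for CO2 without LPS were ribosome biogenesis, integrated stress response, mitochondrial transcription and mitochondrial ribosome genes. The share of genes with the same sign in both CO2 effects was 69.6% over all genes tested, against 90.8% of those called in either, and 83.3 to 93.5% of those with 1 library left out.

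With 1 library left out, counts ranged from 0 to 511, 271 to 1804, 3116 to 4371, 4652 to 5923, 1 to 37 and 1664 to 3005, and called lists in the interaction from 3 to 10. The difference in mitochondrial share ranged from 0.887 to 1.41 points without LPS, 1.04 to 1.98 with LPS and 1.06 to 1.53 pooled. Gene values named in the text gave 1762 comparisons with other settings, of which 1711 kept direction and side of the threshold, 39 became weaker, 10 stronger and 2 reversed; with 1 library left out these were 1602, 203, 5 and 2 of 1812. Those that reversed had not passed the test: MT-ND3 after GC and length correction (−0.0071 without LPS, −0.0032 averaged) and without 5% CO2 replicate 1 (−0.0401 for CO2 without LPS, up to 0.14 with another library left out), and IL1B for CO2 with LPS without 10% CO2 with LPS replicate 1 (−0.00095, up to 0.26 with another left out). No scaling moved the share of higher calls by over 10 points or the median of all genes by over 0.1. Depth limits genes near the floor of 3 counts, such as IL6 without LPS.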

Other observations

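The tests of the mitochondrial transcripts and of GC content in the CO2 calls with LPS were chosen only after the result was seen; the splits were planned, except those that move pairs of libraries together. Camera at the preset correlation called further lists between CO2 levels, none of which passed with an estimated correlation. The values are for LPS-treated cells unless stated. Of 36 lysosome and autophagy genes ULK1, the kinase that starts autophagy (−0.62 ± 0.10), and GABARAPL1 (−0.89 ± 0.18) fell, also 2 adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.574 with an estimated correlation). Of 11 LXR targets 2 fell, SREBF1 (−0.62 ± 0.14) among them, or 3 adjusted over the list alone (0.0325, and adjusted p = 0.542 with an estimated correlation). Of 74 nuclear OXPHOS genes 2 rose with LPS and 0 without, and 0 adjusted over the list alone in both (camera adjusted p = 0.000824 and 0.000247, and adjusted p = 0.739 and 0.695 with an estimated correlation). Cytosolic ribosomal protein genes had 0 of 75 called at either LPS level (medians 0.08, camera adjusted p = 0.00545 and 0.000954, and adjusted p = 0.839 and 0.792 with an estimated correlation). Cell cycle genes had 2 rises and 2 falls of 44, the same counts adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.839 with an estimated correlation), and histone genes 1 rise of 16 (0.0194, and adjusted p = 0.542 with an estimated correlation). Hypoxia genes without LPS had 0 of 29 called and 1 fall adjusted over the list alone (0.00686, and adjusted p = 0.441 with an estimated correlation). For CO2 with LPS, calls were lost for the lysosome list without 5% CO2 with LPS replicate 1 (0.0881) or 10% CO2 with LPS replicate 3 (0.0664), and for LXR targets without 5% CO2 with LPS replicate 1 (0.0771) or 10% CO2 with LPS replicate 2 (0.087). The cell cycle list was lost without 5% CO2 with LPS replicates 2 or 3 (0.209 and 0.208) or 10% CO2 with LPS replicate 1 (0.349), and the histone list without that last library (0.122). Cytosolic ribosomal protein genes were lost for CO2 with LPS without 5% CO2 with LPS replicate 2 (0.14) and for CO2 without LPS without 5% CO2 replicate 3 (0.274). SREBF1 was lost without 5% CO2 with LPS replicate 1 or 2 (0.0608 and 0.0734) or 10% CO2 with LPS replicate 2 (0.0964).

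Few markers of other cell types were tested. T and NK cell markers had 5 tested members and a median of −0.40 at each LPS level, 2 falls adjusted over the list alone at each level, and TRAC the 1 call with LPS (−1.43 ± 0.32, camera adjusted p = 0.0477 with LPS and 0.0664 without, and adjusted p = 0.357 with LPS with an estimated correlation). For CO2 with LPS that list was lost without any library except 5% CO2 with LPS replicate 2 and 10% CO2 with LPS replicate 1 (adjusted p 0.0532 to 0.143), and TRAC without 5% CO2 with LPS replicate 2 (0.0638) or 10% CO2 with LPS replicates 2 and 3 (0.061 and 0.0512). B cell and stromal or endothelial markers had 0 calls by CO2 at either LPS level, apart from 1 rise of a B cell marker with LPS adjusted over the list alone. Epithelial (3) and neutrophil (4) markers were too few for a set test. Adjusted over the list alone 1 epithelial marker fell at each LPS level (median −0.55 without LPS). With LPS 1 also fell over all genes, MUC1, named after its values were seen, and neutrophil markers had 0 calls over all genes but 2 rises and 1 fall adjusted over the list alone. No erythroid marker was tested (0). Camera did not call the lists for CO2 without LPS and with LPS of acid-base transport (adjusted p = 0.776 and 0.856), glycolysis (0.295 and 0.0668), the tricarboxylic acid cycle (0.494 and 0.233), fatty acid oxidation (0.941 and 0.853), the unfolded protein response (0.157 and 0.856), NRF2 targets (0.494 and 0.76), p53 targets (0.0728 and 0.262), the TLR pathway (0.244 and 0.905), cytokines (0.136 and 0.124), inflammasome genes (0.937 and 0.76), Wnt signalling (0.811 and 0.856), circadian genes (0.854 and 0.541) and nuclear-retained RNAs (0.518 and 0.853).

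The rise of mitochondrial mRNAs at 10% CO2 may be technical or may follow the CO2 level. A GC trend as the whole cause is argued against by the median of the 13 changes over both LPS levels, 0.82 after the GC correction and 0.87 before it (median SE 0.203). A single factor for all transcripts of the organelle, as a difference in its share of the RNA would give, stays open. The SD among the 13 changes was 0.271 (exact permutation p = 0.005, the smallest these can give, with 0.248 the highest in other regroupings), but those regroupings ignore that replicate numbers may pair libraries. With both libraries of a number moved together the exact permutation p = 0.1, the smallest those 10 splits can give (highest other SD 0.218). Gene length cannot be told apart with 13 genes, since its Spearman correlation with the change was 0.176 across genes (permutation p = 0.564). RNA quality stays open, and so does an effect of CO2 as a hypothesis.

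The CO2 calls in LPS-treated cells might come from GC content. After the GC correction 81.8% of them, 1174 of 1435, were still called in the same direction, which argues against a GC trend as the whole cause and leaves it open for the rest.

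Other splits of the 6 libraries are too few for a share under 0.05. In each of the 4 pairwise contrasts 1 of 10 splits, the real one, gave as many calls. The real and the highest other counts were 240 and 13 for CO2 without LPS, 1435 and 0 with LPS, 4092 and 0 for LPS at 5% CO2 and 5773 and 0 at 10% CO2. For CO2 averaged over LPS 1 of 100 regroupings gave as many (2748, highest other 2037). The regrouping with 2037 keeps the real CO2 labels at 1 LPS level, and the highest count with real labels at neither level was 232. These regroupings ignore that replicate numbers may pair libraries at 10% CO2. With both libraries of a number moved together there are 10 splits, too few for a share under 0.05 (2748, highest other 6). For the interaction 4 of 100 gave at least the real 4 calls, the real one included, and the highest other called 2037. These regroupings remove any CO2 effect, not the interaction alone, and the others with as many calls keep the real CO2 labels at 1 LPS level. Other regroupings that keep the real labels at 1 LPS level called from 0 to 2 genes, and the cause of this difference was not tested. Since the regroupings remove any CO2 effect, the share says nothing on chance for the 4 genes. With both libraries of a number moved together, 1 of 10 splits, the real one, gave as many interaction calls (highest other 0). Those 10 splits are too few for a share under 0.05 and also remove any CO2 effect.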
